A study of Nematostella vectensis with 136 samples.

How the data were processed

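Whole-organism RNA was sequenced from 136 samples of adult *Nematostella vectensis* in 2 arms (LD and DD), 17 time points per arm and 4 replicates, lettered A to D, per arm and time point. Per the labels' protocols, animals were preserved in RNAlater, RNA was extracted with the Ambion RNAqueous kit, and libraries were made after Meyer et al. The authors deposited one table of whole-number counts per gene, 24384 genes by 136 libraries, with no normalization. Bowtie2 is named without a version per the submitters' processing notes, and the genome is credited to Putnam et al. per the labels; the counting tool, its strand setting, the handling of reads shared between similar genes and the gene models are not given in the sources used here. Genes with near-identical copies or overlapping neighbours may therefore hold shared reads. Each column was matched to its sample by the sample's title. Per the labels, T1 to T12 of both arms were sequenced on lane 5 and T13 to T17 on lane 7, so lanes do not separate the arms.

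Groups came from the labels (arm and time point, 34 groups). Removal of the light cycle was placed between T6 and T7 from the sampling scheme in the labels. The table of gene names given for the organism matched 0 of the identifiers, so the gene lists chosen beforehand, which rest on descriptions, could not be tested, and the identifiers are printed without names or positions.

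Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the 34 groups, which left 10257 genes, libraries were scaled with TMM factors, and 1 model with 34 group means and 102 residual degrees of freedom was fitted to all libraries by quasi-likelihood (glmQLFit with a trended dispersion, glmQLFTest). All comparisons are contrasts of those means: the mean of LD minus the mean of DD over T1 to T6 or over T7 to T17; the change in LD minus the change in DD, T7 to T12 against T1 to T6 and T13 to T17 against T1 to T5; LD minus DD at each time point; and the least-squares cosine and sine components of a 24 h cycle within an arm and period, tested jointly, with differences between arms or periods. A log2 amplitude is the length of that pair of components, its SE is the amplitude divided by the square root of 2 times the F statistic, and for a difference or change the length of the difference of the components is given. Benjamini-Hochberg adjustment ran over the tested genes within each contrast, with a threshold of 0.05. CPM values use TMM-scaled library sizes; means ± SD leave out the 3 libraries with totals under 179339. For genes whose libraries in some groups are all at 0, fitted log2 values depend on the prior count of the fit and are not printed; their CPM are.

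The tests, contrasts, the rule for named genes and a list of other settings to try were fixed before the data were examined. With no gene names, the rule allowed at most 2 identifiers that rose and 2 that fell per comparison, the largest by log2 difference among called genes with a mean log2 CPM of at least 2; for 24 h tests up to 4 with the largest amplitude, and for the change of the component the 2 with the largest rise and the 2 with the largest fall of amplitude. That test compares both components and so responds to a shift of the peak too. Those settings were DESeq2 1.42.0, RLE factors, library size alone, no filter beyond 1 count, a filter of 10 counts in most libraries, a fit of only the libraries of a comparison, the replicate letter as a block, leaving out each letter, leaving out the 3 shallow libraries, a linear trend, any difference among the 6 first-day time points, single days after removal and T7 counted before removal. Added after seeing the data were limma-voom (limma 3.58.1), edgeR's newer quasi-likelihood fit, the fit without the 15 libraries above the midpoint of the programme A score, the programme scores as covariates, leaving out single libraries, and choosing first-day 24 h genes on replicates A and B to measure them in C and D. Programmes are clusters (average linkage on 1 minus the correlation, joined below 0.5, at least 20 genes) of the 400 genes with the most variable log2 CPM (prior count 2) over libraries above 200000 counts; programme A has 131 genes and programme B 27.

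Depth and the spread between libraries set what could be seen. The total per library had a median of 538017, the largest gene took 2.19% of all counts and the top 10 genes 9.75%. Both tests were checked on counts simulated from the real means, library sizes and dispersion trend (9753 genes after the filter), with 200 genes changed for each comparison. Genes were drawn independently, without extra spread of single genes or co-varying groups, and depth was not varied. The rates below hold for such counts and may be better than in the real libraries. For the first-day level difference edgeR recovered 84% of genes changed by 1 on the log2 scale and 26% of those changed by 0.5; for the first-day 24 h component in LD 76% and 8% at amplitudes of 1 and 0.5; and for the component after removal 96% and 40%. False calls were 8 of 159, 7 of 146 and 7 of 173. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.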

Results

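RNA was measured in whole adult starlet sea anemones, *Nematostella vectensis*, a cnidarian. Animals had lived for 1 month either under a light:dark cycle (LD) or in constant darkness (DD), and were then sampled every 4 h at 17 time points, T1 to T17, with 4 replicates per arm and time point. The light cycle was taken away from the LD arm after the first day. The last part of the series thus compares animals that had just lost their cycle with animals kept in constant darkness for at least 1 month. The light history of the DD animals before that month is not given. The labels give the first 24 h and then 44 h more, which puts T1 to T6 before removal and T7 to T17 after it; clock times are not given, and peak times here are hours after T1. The 136 libraries held 68 per arm. Total counts per library had a median of 538017 and ranged from 2185 to 749294. LD libraries had a median total of 551918.5 and DD libraries one of 528846. Under 179339, a limit relative to the median, lay 3 totals, those of DD T4 replicate B (2185), LD T14 replicate D (27546) and DD T1 replicate D (140371); the lowest of the other totals was 207665. Counts of replicates of one group differed beyond sampling noise in all pairs tested, shallow libraries left out, with a chi-square per degree of freedom of at least 2.93, so each library was counted once. The labels do not say whether a replicate was 1 animal or several, nor whether replicates came from separate cultures, and p-values measure the spread between these libraries. The files do not pair the gene identifiers with names, so genes are given by identifier.

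Light-cycled animals differed from constant-dark animals in the mean level of 59 of 10257 genes over the first day, 49 of them higher in LD. NVE8085 had the largest difference: 69.0 ± 66.4 CPM (counts scaled to a common library size; SD, n = 24) in LD against 2.98 ± 2.69 (SD, n = 22) in DD, a log2 difference of 4.01 ± 0.32 (SE). NVE24652 was higher by 2.56 ± 0.34 on the log2 scale, at 25.5 ± 26.9 CPM in LD and 3.51 ± 3.13 in DD. Lower in LD were NVE8689, with a log2 difference of -1.60 ± 0.34, and NVE25138, with -1.33 ± 0.35, the latter at 294.5 ± 207.9 CPM in LD and 735.5 ± 288.7 in DD. Each of these 4 genes kept its direction at 6 of 6 time points. The comparison asks which genes differ, in their level averaged over a day, between animals under a light cycle and in constant darkness. Light exposure itself differed between the arms too, and was not told apart from its cycle. Adjusted p-values from edgeR's quasi-likelihood test were 7.98e-19 for NVE8085, 5.16e-08 for NVE24652, 0.00358 for NVE8689 and 0.0479 for NVE25138. The count was 91 with DESeq2 and 22 without replicate C of every group. NVE25138 lost its call without the 15 libraries described below, though its log2 difference was then -1.355, about the same. Adjusted p-values of NVE25138 ranged from 0.000762 to 0.286 over its alternatives.

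**Figure D1:**
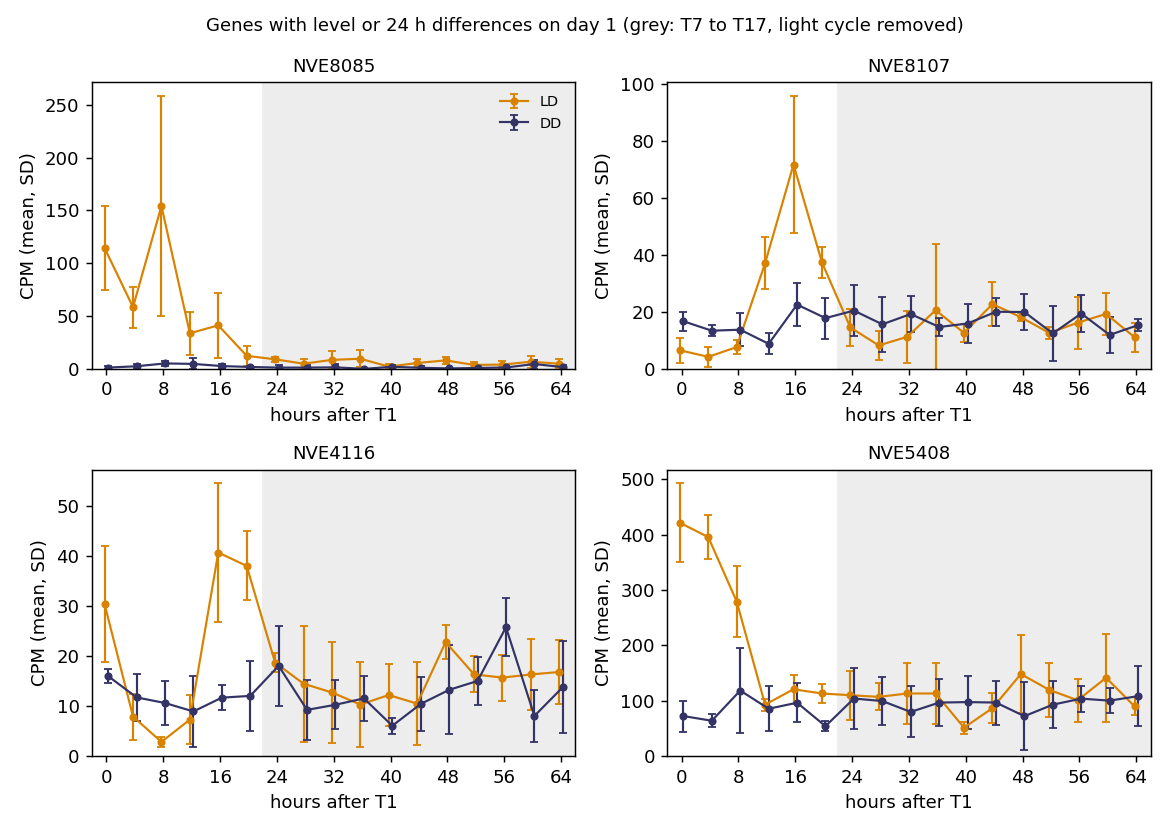
Mean CPM (y axis, error bars SD, up to 4 libraries per point) of 4 genes against hours after T1 (x axis) in LD (orange) and DD (blue), with T7 to T17 shaded. The LD line leaves the DD line on the first day and lies nearer to it afterwards. NVE8107 averaged 27.4 CPM in LD and 15.8 in DD over T1 to T6, then 15.3 and 16.8 over T7 to T17. NVE8085 still averaged 6.14 CPM in LD and 1.39 in DD over T7 to T17.

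Over the same day, 14 genes in LD varied with a 24 h component, and their peaks were spread over the cycle. NVE8107 rose from 4.22 ± 3.44 CPM at T2 to 71.7 ± 23.9 at T5 (SD, n = 4), with a fitted log2 amplitude of 2.16 ± 0.19 (SE) and a peak at 15.8 h. NVE4116 peaked at 19.8 h with an amplitude of 1.93 ± 0.21, moving from 2.87 ± 0.986 CPM at T3 to 40.8 ± 13.9 at T5. NVE12898 peaked at 18.6 h (1.98 ± 0.40), at 64.1 ± 71.3 CPM at T5 and 3.07 ± 2.78 at T3. NVE14677 peaked at 3.2 h (1.60 ± 0.28), falling from 188.9 ± 65.2 CPM at T1 to 25.6 ± 9.17 at T4. In NVE8107, NVE4116 and NVE14677 all 4 libraries at the highest time point lay above all 4 at the lowest; in NVE12898, 3 of 4 did. Of the 14 genes, 7 also belonged to the 59 with a level difference between the arms. Adjusted p-values (edgeR) were 5.1e-15 for NVE8107, 7.84e-11 for NVE4116, 0.000918 for NVE14677 and 0.0115 for NVE12898. A single cycle does not tell a rhythm from a change that happened once: with a linear trend in the fit 4 genes were called, while 1.52% of tested genes differed among the 6 time points in any shape. NVE14677 then had an adjusted p of 0.651, in a range of 6.36e-13 to 0.651 over its alternatives. NVE12898 lost its call in 6 of 16 alternatives, with an adjusted p of 0.524 with the trend, 0.59 without replicate D of every group and 0.832 with the scores of 2 co-varying gene groups, programmes A and B, as covariates, in a range of 0.00105 to 0.832. It stood at 158.7 CPM in LD T6 replicate D and at most 17.3 in the others of that group, and without that library its adjusted p was 0.248. LD T6 replicate D and LD T5 replicates C and D had programme B scores of 7.56, 7.62 and 7.25 against a median of 2.70. DESeq2 called 99 genes and edgeR's newer quasi-likelihood fit 88.

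In DD no gene passed the test for a 24 h component on the first day. In edgeR 425 genes had an unadjusted p under 0.05, where 513 would be expected by chance; limma-voom also called 0 genes and DESeq2 26. The 14 genes rhythmic in LD had a median amplitude of 0.396 in DD on that day, against 1.29 in LD. A direct test of the difference between arms was passed by 3 genes, NVE8107, NVE4116 and NVE5408, with differences of 2.07 ± 0.28, 1.76 ± 0.30 and 1.27 ± 0.24 between the fitted 24 h components (log2, SE). NVE5408 stood at 422 ± 71.6 CPM at T1 and 93.2 ± 10.9 at T4 in LD, and averaged 82.2 ± 42.4 CPM in DD. Adjusted p-values (edgeR) were 1.19e-06, 0.00128 and 0.0181 in the same order. The call of NVE5408 ended without the 15 libraries described below, where its difference was 1.25, nearly the same as with all libraries. Adjusted p-values of NVE5408 ranged from 0.00161 to 1 over its alternatives. The count was 0 with a linear trend and 8 with DESeq2.

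The 24 h components of the first day were smaller in LD once the cycle was gone. The 14 genes were chosen on their first-day amplitudes, which by itself makes a smaller one in another period probable; all 14 had a smaller amplitude over T7 to T17, with medians of 1.29 and 0.267 (log2) beside a median of 0.204 over all tested genes. In a test added after seeing the data, 8 genes were chosen with limma-voom on replicates A and B alone, and their components in replicates C and D were measured along the peak time found in A and B. The median there was 1.09 on the first day and 0.236 over T7 to T17, smaller in 8 of 8 genes, with a median difference of 0.856 (95% bootstrap interval over genes 0.605 to 1.34). None of the 14 was called rhythmic after removal by edgeR, where 2 had an unadjusted p under 0.05, nor by DESeq2 or limma-voom, and 8 passed the test of the change itself, NVE8107 and NVE4116 among them with changes of 1.95 ± 0.24 and 1.88 ± 0.26 (SE). Their adjusted p-values were 1.36e-07 and 2.94e-06. With a linear trend the change of NVE8107 was 1.69 with an adjusted p of 0.132, in a range of 3.81e-10 to 0.132 over its alternatives, while NVE4116 passed in all 17 of its alternatives, at 3.48e-07 to 0.0029. Without the 15 libraries described below, 2 of the 14 passed the test of the change, these same genes, with adjusted p-values of 0.000607 and 9.92e-05.

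**Figure D2:**
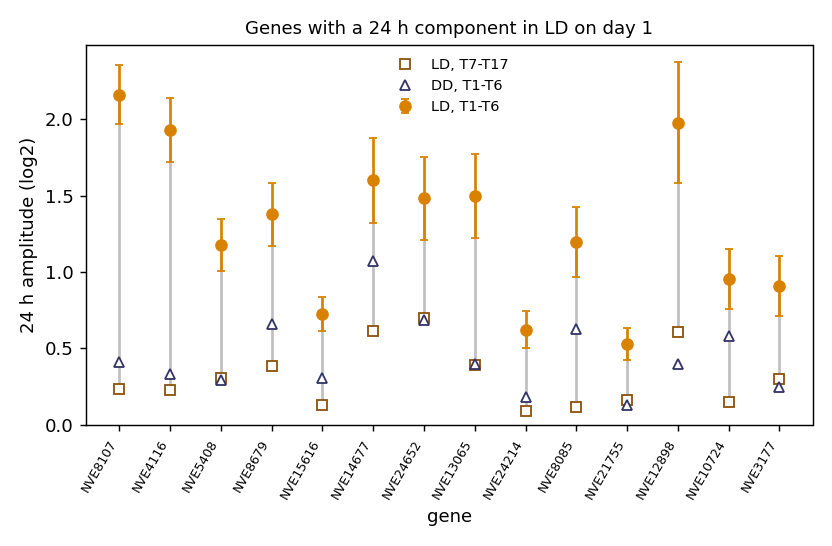
Fitted 24 h amplitude (y axis, log2) of the 14 genes rhythmic in LD on the first day (x axis), in LD over T1 to T6 (filled circles, error bars SE), in LD over T7 to T17 (squares) and in DD over T1 to T6 (triangles). All 14 squares lie below their circles; for NVE8107 the amplitude was 2.16 on the first day and 0.233 afterwards.

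Level differences shrank too, in most but not all genes. For the 49 genes higher in LD on the first day, the median log2 difference between arms went from 0.901 to 0.16 over T7 to T12 and 0.128 over T13 to T17; for the 10 lower genes it went from -0.803 to -0.325 and -0.282. These genes were chosen on their first-day values. The change itself was past the threshold for 6 (T7 to T12) and 9 (T13 to T17) of the 49 genes, and for 0 of the 10 in either period. A set of 16 genes chosen on replicates A and B alone went from 1.57 to 0.632 and 0.968 in replicates C and D. Of those, 15 were higher in LD, so that check hardly covers the lower genes. NVE8085 averaged 6.14 ± 4.90 CPM in LD (SD, n = 43) and 1.39 ± 2.26 in DD (n = 44) over T7 to T17. That difference was still past the threshold (edgeR, adjusted p = 2.17e-05), and the change of NVE8085 at removal was not past it in either period. Of the lower genes named above, NVE8689 had a log2 difference of -0.25 ± 0.24 (SE) over T7 to T17. NVE25138 lay at -1.225 ± 0.264 over T7 to T17 as a whole. Its log2 change relative to DD was 0.719 ± 0.496 over T7 to T12 and -0.753 ± 0.547 over T13 to T17, neither past the threshold. The change in LD beyond that in DD was past the threshold for 9 genes in the first cycle after removal (2 rose, 7 fell) and for 16 genes over T13 to T17 (1 rose, 15 fell). NVE8679 fell by 1.78 ± 0.33 (log2, SE) and NVE5408 fell by 1.30 ± 0.24 relative to DD over T7 to T12; the LD mean of NVE8679 was 74.1 ± 48.0 CPM before and 20.6 ± 11.7 after removal, and the DD mean 24.4 ± 15.3 and 26.1 ± 16.0. NVE18005 and NVE7680 rose relative to DD, by 1.97 ± 0.44 and 0.94 ± 0.21. In LD they averaged 19.3 and 25.2 CPM over T1 to T6, then 55.1 and 34.4 over T7 to T12. Their DD means went down, from 24.5 and 32.2 CPM to 14.8 and 22.9. Over T13 to T17 NVE2673 fell by 1.96 ± 0.36 and NVE2059 fell by 1.93 ± 0.45, and NVE3038 rose by 0.82 ± 0.18. The falls and the rise of NVE3038 held at every time point of their period, and NVE18005 and NVE7680 lay above their first-day difference at 5 of 6.

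Adjusted p-values (edgeR) were 0.00236 for NVE8679 and NVE5408, 0.0299 for NVE18005 and NVE7680, 0.000927 for NVE2673, 0.0275 for NVE2059 and 0.0125 for NVE3038. Without the 15 libraries described below, NVE18005, NVE7680 and NVE2059 lost their calls. The log2 changes of NVE18005 and NVE7680 were then smaller, at 0.87 and 0.48, while that of NVE2059 was -1.77, close to its value with all libraries. Adjusted p-values over the alternatives ranged from 0.0105 to 1 for NVE18005, 0.0173 to 1 for NVE7680 and 0.0101 to 0.296 for NVE2059. For NVE3038 they ranged from 0.00679 to 0.336. With T7 counted as the last point before removal, no gene passed over the first cycle in edgeR, where 457 had an unadjusted p under 0.05.

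A group of genes that rose and fell together from library to library accompanied the results after removal. This group, called programme A here, held 131 of the 400 most variable genes, and its score in a library is the mean log2 CPM of its genes. The score lay near its median of 2.40 in most libraries and reached 7.87; in LD T8 replicate A the 131 genes took 4.08% of all counts, against a median of 0.0331%. Above the midpoint of the range lay 13 LD libraries and 2 DD libraries. The LD libraries were replicates A and B of T6, C and D of T7, A and B of T8, A, C and D of T9, A of T14, D of T16, and A and C of T17, and the DD libraries replicate B of T5 and replicate A of T12. Over T7 to T17 the mean score was 3.69 ± 1.93 in LD (SD, n = 43) and 2.60 ± 0.61 in DD (n = 44), which differed in a two-sided permutation test of the arm labels within time points (p = 0.00047, 0.00188 after Benjamini-Hochberg adjustment over 8 programme comparisons). Over T1 to T6 it was 2.98 ± 1.23 (n = 24) and 2.71 ± 0.88 (n = 22; permutation p = 0.353, adjusted 0.353). The arms differed in each of the 2 sequencing lanes, by 0.71 over T1 to T12 (permutation p = 0.012, adjusted 0.024) and by 1.05 over T13 to T17 (permutation p = 0.00657, adjusted 0.0175).

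**Figure D3:**
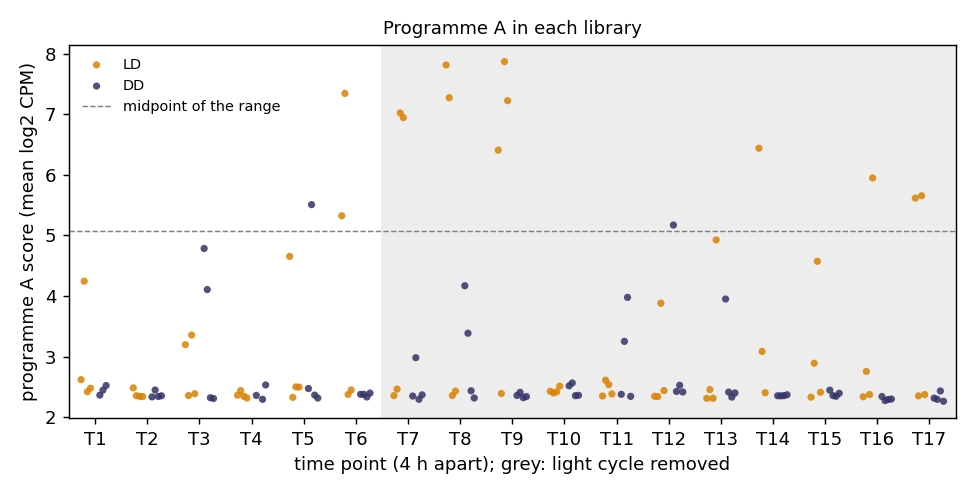
Programme A score (y axis, mean log2 CPM of 131 genes) of each library against time point (x axis), LD in orange and DD in blue, without the 3 shallow libraries, with the midpoint of the range as a dashed line. Of the 12 LD libraries at T7 to T9, 7 lie above the line and 5 below it, and the highest DD library at those times has a score of 4.17.

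After removal, 898 genes in LD had a 24 h component, and 662 of them peaked between 0 and 8 h in the cycle, the hours of T7 to T9. Programme A supplied 118 of the 898. The 4 genes with the largest amplitude, NVE25376, NVE12125, NVE11188 and NVE4446, were close to absent in most libraries: NVE12125 averaged 250 ± 456 CPM in LD over T7 to T17 (SD, n = 43) with a median of 2.88, and NVE25376, NVE11188 and NVE4446 each had a median of 0 beside means of 63.8 ± 127, 80.5 ± 163.9 and 8.97 ± 18.8. Adjusted p-values (edgeR) were 0.0071, 0.00546, 0.016 and 0.0116 for NVE25376, NVE12125, NVE11188 and NVE4446. Without the 15 libraries above the programme A midpoint, an alternative chosen after seeing the data, all 4 lost their calls and 3 genes were called, NVE10468, NVE16955 and NVE19960, the last 2 named after their values were seen; 1 LD library was then left at T9 and 2 at T7 and at T8. With the programme scores as covariates and all libraries kept, 39 genes were called. NVE25376, NVE12125 and NVE11188 are themselves genes of programme A. For such genes a loss under either of these 2 settings was built into the choice of score and is no independent test. DESeq2 called 294 genes, limma-voom 315, a linear trend gave 103 and the fit without replicate A of every group 2, while RLE factors gave 1653 and T7 to T12 alone, all on one lane, 1437; the 5 time points of the other lane cover less than a cycle. Without the single library LD T8 replicate A edgeR called 299 genes. DESeq2 gave adjusted p-values of 0.394, 0.339 and 0.446 for NVE25376, NVE12125 and NVE11188, and without replicate A they were 0.525, 0.243 and 0.481, and 0.442 for NVE4446. The ranges over their alternatives were 2.64e-05 to 1 for NVE25376, 9.77e-05 to 0.9 for NVE12125, 0.000197 to 1 for NVE11188 and 0.00032 to 1 for NVE4446.

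In DD, 7 genes had a 24 h component over the same time points, with 5 of the peaks between 12 and 16 h. NVE10468 had an amplitude of 1.63 ± 0.27 (log2, SE) with a peak at 10.2 h, NVE7148 one of 1.25 ± 0.19 at 13.4 h, NVE6036 one of 1.19 ± 0.24 at 14.8 h and NVE18057 one of 0.63 ± 0.12 at 13.1 h. NVE10468 stood at 17.9 ± 7.31 CPM at T13 and 328 ± 260 at T17 (SD, n = 4), with all 4 libraries at T17 above those at T13. NVE7148 and NVE6036 were also highest at T17, at 400.1 ± 679.8 and 85.9 ± 148.5 CPM, means carried by replicate A with 1420 and 308.3 CPM against at most 74.2 and 20.6 in the other libraries. Of the 7 DD genes, 4 were also among the 898 of LD, where 0.613 would be expected of independent lists (Fisher's exact test, two-sided, p = 0.00165), and none of the 14 first-day genes was (1.23 expected, p = 0.627). Adjusted p-values (edgeR) were 0.000758, 0.000222, 0.0297 and 0.0135 for NVE10468, NVE7148, NVE6036 and NVE18057. Without DD T17 replicate A 5 genes were called, and NVE7148, NVE6036 and NVE18057 had amplitudes of 0.99, 0.77 and 0.59 with adjusted p-values of 0.00143, 0.32 and 0.063. T7 to T12 alone gave 1 gene, NVE10468; the adjusted p-values of NVE7148, NVE6036 and NVE18057 were then 0.573, 0.884 and 0.577, in ranges of 0.000116 to 0.573, 0.00713 to 0.884 and 0.00161 to 0.577 over their alternatives. The DD count was 38 with DESeq2, 2 with a linear trend and 0 without replicate C of every group, where NVE10468 had an adjusted p of 0.201 in a range of 0.000303 to 0.201.

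The change of the 24 h component in LD passed the threshold for 526 genes, 44.5% with a larger amplitude after removal and 55.5% with a smaller one. A shift of the peak passes this test as well as a change of amplitude, and the amplitudes alone were not tested against each other. Among called genes with a mean log2 CPM of at least 2, the amplitude fell most in NVE8107, from 2.16 to 0.233, and in NVE4116, from 1.93 to 0.226. Among those with a larger amplitude, NVE10468 changed by 1.58 ± 0.43 (log2, SE), from an amplitude of 0.171 on the first day to 1.41 afterwards, and NVE881 changed by 1.89 ± 0.44. Programme A genes made up 96 of the 526. Adjusted p-values (edgeR) for NVE10468 and NVE881 were 0.0386 and 0.0143. Without the 15 libraries most of the 526 calls ended, and NVE881 was not tested. NVE8107 and NVE4116 kept their calls, as did NVE1728, named after its value was seen. NVE10468 lost its call, though its change was then 1.75 against 1.58 with all libraries. Adjusted p-values of NVE10468 ranged from 0.0117 to 0.452 over its alternatives, and those of NVE881 from 0.000207 to 0.723. With the programme scores as covariates the count was 5, and with a linear trend 3.

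When both arms were dark, 864 genes differed in mean level over T7 to T17, 590 higher in LD and the other 31.7% lower. The genes with the largest excess in LD, NVE26091 and NVE16839, were at a median of 0 CPM in both arms; NVE26091 averaged 35.9 ± 72.7 CPM in LD (SD, n = 43) and 1.19 ± 4.78 in DD (n = 44), and NVE16839 15.1 ± 28.1 and 0.544 ± 2.07. Lower in LD were NVE23371, by -1.45 ± 0.43 (log2, SE), and NVE23460, by -1.35 ± 0.33, the latter at 260 ± 403 CPM in LD and 530 ± 369 in DD. Time points in the stated direction numbered 9, 10, 8 and 10 of 11 for NVE26091, NVE16839, NVE23371 and NVE23460. Their adjusted p-values (edgeR) were 0.047, 0.000372, 0.0191 and 0.00401. Within one sequencing lane, 4.09% of tested genes differed over T7 to T12, and within the other 2.10% over T13 to T17, against 8.42% over both. The share of calls higher in LD was 68.3% with TMM factors, 85.8% with RLE factors and 82.1% with library size alone. Without the 15 libraries most of the 864 calls ended. NVE26091 and NVE16839 are genes of programme A, by which those libraries were picked. That NVE26091 lost its call there was therefore built in, and NVE16839 was not tested. NVE23371 and NVE23460 lost their calls too, but their log2 differences were -1.88 and -1.20, against -1.45 and -1.35 with all libraries. Adjusted p-values over the alternatives ranged from 0.00272 to 1 for NVE26091, 0.0145 to 0.447 for NVE23371 and 0.000806 to 0.289 for NVE23460. NVE16839 lost its call in 5 of 17 alternatives.

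Taken time point by time point, the arms differed in 777 genes at 1 or more of the 17 times, 693 of them at T7, T8 or T9. The counts were 126 at T7, 240 at T8 and 608 at T9, with 8, 5 and 48 of them lower in LD, and then 0 at T10, T11 and T12, where 391, 505 and 289 genes had an unadjusted p under 0.05 and DESeq2 called 0, 5 and 6. At T7, T8 and T9 limma-voom called 0, 0 and 12 genes, while DESeq2 called 2.59%, 2.87% and 4.00% of the 10257 genes. On the first day they were 8, 8, 1, 0, 3 and 7 from T1 to T6, each called gene being higher in LD. At T14 66 genes differed, 44 of them lower in LD, and 5 did so without the 3 shallow libraries, of which LD T14 replicate D is 1. Shallow libraries were not eligible for the 15 of programme A. In LD T14 replicate D that programme took 0.984% of counts, against 0.597% in DD T12 replicate A, which is among the 15. At T9 the median of all genes moved from -0.01 with TMM factors to 0.128 with RLE factors and 0.105 with library size alone. Without the 15 libraries the counts at T7, T8 and T9 were 0 in edgeR, with 723, 451 and 598 genes at an unadjusted p under 0.05 and at most 2 LD libraries left at each, and the count over all times was 62; limma-voom with all libraries gave 77.

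**Figure D4:**
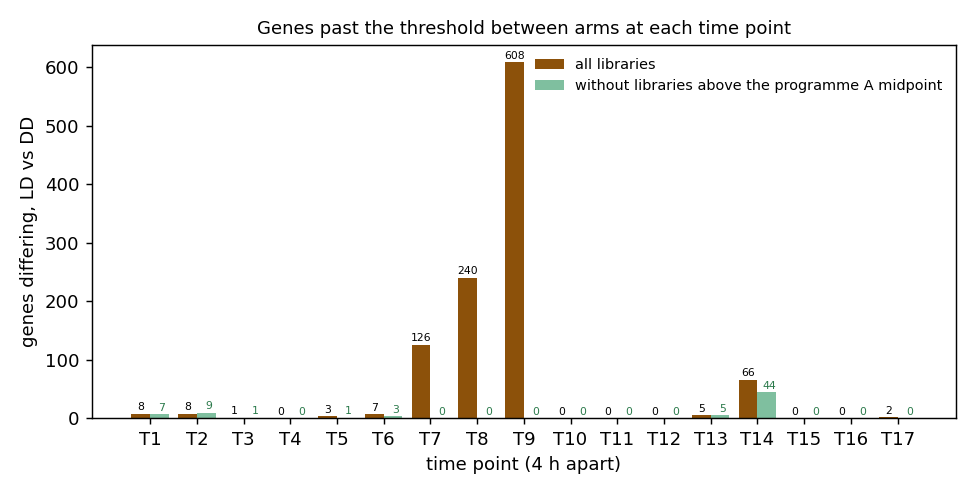
Number of genes past the threshold between LD and DD (y axis, linear from 0) at each time point (x axis), with all libraries (brown) and without the 15 libraries above the programme A midpoint (green). The counts of 126, 240 and 608 at T7 to T9 stand at 0 without those libraries, and the count of 66 at T14 stands at 44. The shallow LD T14 replicate D, with 0.984% of its counts in programme A, was kept in both fits.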

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

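The tests of programme A against the response of every animal and against an uneven state, and the tests of chosen extremes, of the lane, of the DD arm and of other splits, were chosen only after the result was seen; the test of depth was set before its result was.

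Single libraries stood far from the other 3 of their group (gap over range above Dixon's 95% value) in 2 of 34 groups by total count, where about 1.7 would be expected by chance. DD T4 replicate B had 2185 counts against 520432 to 595935, and LD T10 replicate B had 435177 against 394700 to 400516. By the programme A score 11 of 31 groups with 4 deep libraries held such a library, where about 1.6 would be expected. In LD these were T1 replicate B with a score of 4.24, T2 replicate A with 2.48, T5 replicate A with 4.65, T12 replicate C with 3.88, T13 replicate D with 4.92 and T16 replicate D with 5.95. In DD they were T2 replicate B with 2.45, T5 replicate B with 5.51, T7 replicate B with 2.98, T12 replicate A with 5.17 and T13 replicate A with 3.95. The scores of the other libraries in those groups ran from 2.29 to 2.75. LD T2 replicate A and DD T2 replicate B lay within that range, near the overall median of 2.40. They were flagged because the others of their groups were nearly equal, at 2.34 to 2.35 and 2.33 to 2.35. Chance flags about 1 group in 20 if scores are normally distributed, which was not tested.

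Programme A, 131 genes near silence in most libraries and abundant in a few, was high mostly in LD libraries, and many of the genes called after removal were its members or lost their call without those libraries. Depth was argued against: with every library thinned to 207665 counts, 13 of the 15 libraries above the midpoint stayed above it. A response shared by every LD animal was also argued against, since 7 of the 12 LD libraries at T7 to T9 lay above the midpoint and the others went down to 2.36, and since 2 LD libraries at T6, before removal, lay above it. What stays open is a state present in some animals and carried more often in the LD arm, a hypothesis found and tested on the same libraries. The score differed between arms over T1 to T17 (two-sided permutation test within time points, p = 0.00045), but that test does not address timing. LD libraries above the midpoint numbered 2, 2, 2 and 3 at T6 to T9, and 0 at each of T1 to T5 and T10 to T13. These counts depend on the midpoint of 5.065: LD T5 replicate A and LD T13 replicate D lay below it with scores of 4.65 and 4.92. Whether the grouping in time goes beyond chance was not tested, so it does not decide for or against a state merely more frequent in LD. A response confined to some LD animals at T6 to T9 was not tested either. Whether the light regime, or a difference between cultures that the labels do not record, set the arms apart was not tested.

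In limma-voom, leaving out 1 such library at a time moved several counts. Of 315 genes with a 24 h component in LD after removal, the count was 113 without LD T8 replicate A, 121 without LD T8 replicate B and 133 without LD T14 replicate A. The count for the change of the component was 118 and became 52, 59 and 39 without the same libraries, 50 without LD T6 replicate B, and 73 and 72 without LD T9 replicates C and D. The level difference after removal went from 3.95% of tested genes to 2.33% without LD T8 replicate A and to 2.24% without LD T14 replicate A. The change at removal over T7 to T12 went from 8 to 14 without LD T6 replicate B and to 5 without LD T9 replicate D, and that over T13 to T17 from 16 to 9 without LD T14 replicate A. The count over single time points went from 77 to 32 without the shallow LD T14 replicate D.

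Effects that differed between the arms or between periods under a test of the difference were 3 genes for the first-day 24 h component, with lengths of 2.07 (NVE8107), 1.76 (NVE4116) and 1.27 (NVE5408) on the log2 scale. For the change of the component in LD at removal they were 526 genes, with 1.95 for NVE8107, 1.88 for NVE4116, 1.58 for NVE10468 and 1.89 for NVE881. For the change of level at removal they were 9 genes over T7 to T12, with 1.97 (NVE18005), 0.94 (NVE7680), -1.78 (NVE8679) and -1.30 (NVE5408), and 16 genes over T13 to T17, with 0.82 (NVE3038), -1.96 (NVE2673) and -1.93 (NVE2059).

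The shrinking of first-day differences after removal was weighed against explanations other than the lost light cycle. The 16 genes used for this included 15 higher in LD, so genes lower in LD are hardly covered. Genes chosen for extreme first-day values would shrink by themselves. Yet 16 genes chosen on replicates A and B had a median first-day difference of 1.57 in replicates C and D. That median was 0.632 over T7 to T12 and 0.968 over T13 to T17. From the first day to T7 to T12 the median shrinkage in replicates C and D was 0.991 (95% bootstrap interval over genes 0.618 to 1.39). No interval was computed for T13 to T17, where the shrinkage was smaller. Resampling genes does not measure the spread between libraries. The sequencing lane was shared by T1 to T12, and within it 14 of the 16 genes shrank. For these 16 genes over T7 to T12, a change in the DD arm was argued against by a median change of 0.075 in DD beside -1.17 in LD. That does not cover T13 to T17, where the DD means of NVE2673 and NVE2059 lay above those of the first day. A hypothesis that goes with these values is that the levels depended on the running cycle or on the light in it, which were not told apart. Time since the first sampling, which no cycled arm controls for, stays open.

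Other splits of the libraries were drawn 100 times, the real one included, with limma-voom: arms exchanged within time points, or time points within arm and period. The real count exceeded all others, 1 of 100 splits and the smallest share possible here, for most results. For levels this held on the first day (real count 52, highest other 2) and after removal (405 and 1). It held for the level changes at removal over T7 to T12 (8 and 1) and T13 to T17 (16 and 3). For the 24 h component in LD it held on the first day (14 and 5) and after removal (315 and 19). It also held for the first-day difference from DD (3 and 2), DD after removal (10 and 1) and the change in LD (118 and 3). The margin was narrowest for the difference from DD, and the shares were not adjusted over the results. The exchange removes every arm or time effect at once, so the splits do not test whether an effect stayed the same at removal. Libraries are taken as exchangeable, though cultures are not recorded. For single time points 4 of 100 splits gave as many genes as the real 77, and the highest gave 240, which points to a structure of the samples. In that split 99.6% of the genes came from T9, with the 3 programme A libraries of T9 in one arm; 15 of the 99 other splits had these 3 together, of which 3 gave as many genes as the real one, and the highest of the splits that parted them gave 40. In the real split 50 of the 77 genes came from T14. For the first-day component in DD the real count was 0, so that all 100 splits gave as many and chance cannot be excluded; the highest was 1.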

How the results depend on the processing

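limma-voom, edgeR's newer quasi-likelihood fit, the fit without the 15 programme A libraries, the programme scores as covariates and the fits without single libraries were chosen after seeing the data; the other settings were planned. Under these settings 101 counts of genes stayed within 1.5 times the main count and 91 did not. Of 571 values of named genes, 405 kept direction and call and 2 turned, while the others kept direction and lost the call. Under the programme covariates the 24 h components after removal in LD of NVE12125 (amplitude 0.299) and NVE11188 (0.241) pointed the other way. Both genes belong to programme A, whose score was a covariate, so the loss of their component was built into that fit. Except where fewer libraries or genes show it, the cause was not tested. Small changes could be missed: in simulated first-day data most changes of 0.5 on the log2 scale were missed at the real depths. Main counts were 59 genes (first-day level), 14 and 0 (first-day rhythm in LD and DD), 3 (rhythm difference), 7 (rhythm in DD after removal), and 9 and 16 (level change at T7 to T12 and T13 to T17). Settings were compared by counts of genes; 4 results and the test of any difference are given as shares of the genes tested under a setting, so that a share near the main one can stand for fewer genes. As shares, main values were 8.75% (rhythm in LD after removal), 5.13% (rhythm change), 8.42% (level after removal) and 7.58% (single time points).

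With DESeq2 the first-day level gave 91 genes, the first-day rhythm 99 in LD and 26 in DD, the rhythm difference 8, the rhythm after removal 3.75% in LD and 38 genes in DD, the rhythm change 2.51% and the level changes 15 and 34. With limma-voom the rhythm in LD after removal was 3.07%, the rhythm change 1.15%, the level after removal 3.95% and single time points 0.751%. edgeR's newer fit gave 88 genes for the first-day rhythm in LD and 11 for DD after removal. RLE factors gave 16.1% and 19 genes for the rhythm after removal in LD and DD and 9.00% for the rhythm change; library size alone kept every count within 1.5 times. No filter gave 4 for DD after removal, 1.05% for the rhythm change and 3 for the level change at T7 to T12. The stricter filter, which tests fewer genes, gave 1 for the rhythm difference, 7.93% and 18 genes for the rhythm after removal in LD and DD, 4.50% for the rhythm change, 9.08% for the level after removal and 5.67% for single time points.

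A linear trend gave 4 genes for the first-day rhythm in LD, 0 for the rhythm difference, 1.00% and 2 genes for the rhythm after removal in LD and DD and 0.0292% for the rhythm change. Any difference among the 6 first-day time points gave 1.52% in LD and 0.0292% in DD. T7 to T12 alone gave 14.0% and 1 gene for the rhythm in LD and DD, 11.9% for the rhythm change and 4.09% for the level after removal; T13 to T17 alone gave 2.10% for the level. With T7 counted before removal the level change at T7 to T12 was 0 and the level after removal 4.24%.

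Only the libraries of a comparison, with fewer samples for the spread, gave 9 genes for the first-day rhythm in LD, 6 for the rhythm difference, 0.429% and 11 genes for the rhythm after removal in LD and DD, 0.0817% for the rhythm change and 0.225% for single time points. Without the 3 shallow libraries the rhythm in DD after removal was 18. Without the 15 programme A libraries the first-day rhythm in LD was 26, the rhythm after removal 0.0247% in LD and 11 genes in DD, the rhythm change 0.0247%, the level changes 2 and 8, the level after removal 0.189% and single time points 0.510%. The programme covariates gave 0.380% and 11 genes for the rhythm after removal, 0.0487% for the rhythm change, 5 for the level change at T7 to T12, 0.292% for the level after removal and 0.448% for single time points. Leaving out each replicate letter, with 3 libraries per group, gave 22 to 40 genes for the first-day level, 9 to 19 and 0 to 0 for the first-day rhythm in LD and DD, 1 to 2 for the rhythm difference, 0.0192% to 7.60% and 0 to 5 genes for the rhythm after removal in LD and DD, 0.0385% to 4.06% for the rhythm change, 0 to 2 and 3 to 9 for the level changes, 2.27% to 6.20% for the level after removal and 1.18% to 7.51% for single time points.

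The replicate letters were not found to pair the libraries: deviations of same-letter libraries of the 2 arms correlated at -0.003 on average, and 10 of 65 pairs exceeded 0.1. With the letter as a block the counts were 55, 14, 0, 3, 7, 8 and 15 genes and the shares 7.83%, 4.33%, 8.13% and 7.49%, in the order of the main values above; no call count moved by over 1.5 times.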

Other observations

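The tests of programme B and of the overlap of both programmes were chosen after the result was seen. Genes with a 24 h component in both arms after removal peaked at nearly the same hours in each. These were NVE10468, NVE16955, NVE18057 and NVE23819, of which NVE16955 and NVE23819 were named after their values were seen. Peaks in LD and DD lay 0.6, 0.1, 0.9 and 0.7 h apart, at 9.6, 13.5, 13.9 and 14.5 h in LD, and amplitudes in LD were 1.41, 0.81, 0.64 and 0.58 on the log2 scale. All 4 kept their DD call without the 15 programme A libraries, and NVE10468 and NVE16955 kept their LD call too. In LD on the first day their amplitudes were 0.17, 0.28, 0.42 and 0.26, and none was called by edgeR. Fitted peaks then lay at 21.8, 3.5, 3.7 and 4.8 h, far from the later ones. In DD on the first day the amplitudes were 1.23, 0.29, 0.46 and 0.38, also not called, with peaks at 18.3 h for NVE10468 and 2.9 h for NVE18057. The shared later peaks thus do not show a rhythm that ran since the first day. Both arms also changed lane after T12, and a shared time course was not tested.

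Of the 864 genes that differed in level when both arms were dark, 21 passed with and without the 15 programme A libraries, and 16 of these were lower in LD, by a median log2 difference of -0.71. On the first day 20 of the 21 had the same direction, and 3 were past the threshold.

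A second co-varying group of 27 genes, programme B, reached a score of 7.62 against a median of 2.70. Above its midpoint lay 18 libraries, 12 of LD and 6 of DD. Its score did not pass a test between the arms over T1 to T17, at 3.56 ± 1.55 in LD (SD, n = 67) and 3.11 ± 1.12 in DD (n = 66; two-sided permutation p = 0.0638, adjusted 0.102 over 8 comparisons). No library lay above the midpoints of both programmes, where 2.03 would be expected if they were independent (one-sided permutation p = 0.099). Exclusive states of single animals are a possible explanation that 15 and 18 libraries are too few to decide; the labels record neither sex nor reproductive state, and the identifiers carry no names to place the genes.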
